A study of Homo sapiens with 75 samples.

How the data were processed

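RNA from 5 lines of diffuse large B-cell lymphoma cells, U2932, HBL1, LY7, DHL6 and DHL4, was measured on Affymetrix HT HG-U133 Plus arrays, 1 array per sample. Each line had 5 groups of 3 arrays: the vehicle DMSO at 0, 6 and 24 h, and R406, an inhibitor of the kinase SYK, at 6 and 24 h. This gave 25 groups and 75 arrays, and every group was taken from the sample labels. The replicates carry the letters A, B and C. The labels do not say whether the letters stand for separate cultures, so all p-values measure only the spread between these samples, which may be technical. The dose of R406 is not given in the sources used here.

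The deposited table holds log2 expression values that the authors made with RMA, per the submitters' processing notes. No version of RMA is given in the sources used here. RMA corrects background, makes the distributions of the arrays equal and summarises the probes of a probe set on the log2 scale. A change that moved most transcripts in 1 direction is therefore not visible in such values as a shift of the whole array. The table has 19598 rows, of which 19536 are gene-level probe sets named by an Ensembl gene identifier, 1 per gene, and 62 are control probe sets. Values ran from 2.17 to 14.76 and the medians of single arrays from 5.84 to 5.97. For arrays there is no count of molecules behind a value, and their number limits the precision. No array was identical to another, and each of the 75 arrays correlated best with an array of its own group over the genes tested.

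The files do not pair the gene identifiers with gene names. The gene table of the reference has 59792 rows, and 0 of them carry an Ensembl identifier. The 23 gene lists and the genes fixed by name before the data were examined, all of them written as gene symbols, were therefore not analysed here. In place of the rule for named genes, which would have taken 10 genes in each direction for the average over the lines at each time and further genes for the other comparisons, 4 identifiers are printed. They are the gene with the highest and the gene with the lowest average log2 fold change at 6 h, and the next such pair at 24 h, among genes with an adjusted p under 0.05 and the same sign in all 5 lines. This reduction was decided after the numbers of called genes were known and before any gene's fold change had been looked at.

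Genes were kept where the highest of the 25 group means lay above 5.89, the median of all values in the table. This left 11745 genes and removed 7791. A linear model with 1 mean per group was fitted to all 75 arrays with limma 3.58.1 in R 4.3.3, which left 50 residual degrees of freedom. Contrasts were tested two-sided with moderated statistics (eBayes), and p-values were adjusted by the Benjamini-Hochberg method within each contrast. Genes with an adjusted p under 0.05 are called changed. R406 was compared with DMSO of the same line and time, because the labels give the vehicle arrays as the account of growth conditions. Further contrasts were the mean of the 5 lines' R406 responses, the difference between the mean response of HBL1 and U2932 and that of DHL4, DHL6 and LY7, the difference between the responses at 24 and 6 h, and DMSO at 6 or 24 h against 0 h. A moderated F-test compared the responses of the 5 lines. The division of the lines is background knowledge on their class and is not in the labels, and with 5 lines a set cannot be separated from its lines. The spread of log2 fold changes over genes was corrected by subtracting the mean squared standard error from its variance. To test for noise at 24 h it was also corrected with the standard error from each line's own R406 and DMSO arrays at 24 h.

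The control probe sets were kept out of the gene tests. Only their values had been planned. Their tests were added after values had been seen, with variances moderated by the prior of the gene fit and Benjamini-Hochberg adjustment over the control measures and the 10 comparisons of line and time, or over the control measures for an average. Spike-in values are means over the probe sets of the bacterial poly-A RNAs or of the hybridisation controls.

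The fit was tested on simulated data made from the real group means and spreads of the 11745 genes, with 200 of them changed. For DHL4 at 24 h it recovered 57.4% of the genes changed by 0.3, 95.5% of those changed by 0.6 and 100% of those changed by 1 on the log2 scale, with 10 false calls. For the average at 24 h it recovered 98.5% at 0.3, with 12 false calls. No gene was called in the simulated contrasts without a change. The simulated noise was independent between genes, and far more genes were called in the real data. These shares and false calls therefore need not hold there.

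Alternatives fixed before the data were examined were cyclic loess normalization, subtraction of each array's median, no filter or a stricter filter at the upper quartile of all values, eBayes with a trend and robust prior, array weights, the replicate letter within a line as a block, each array left out, a separate fit for each line, DMSO at 0 h as the control, each line left out, and the lines as replicates. Under the scaling alternatives the same genes were tested. A mean over several probe sets of a gene was not run, since each gene has 1 probe set.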

Results

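Expression was measured in 5 cell lines derived from diffuse large B-cell lymphoma, a cancer of mature B cells, to describe the response to R406. R406 inhibits SYK, a kinase that carries the signal of the B-cell receptor. Each line was sampled with 3 arrays at 0, 6 and 24 h in DMSO and with 3 arrays at 6 and 24 h in R406, so that each line and time contributes 6 arrays to its comparison. Within groups the correlation of arrays over the 11745 genes tested ranged from 0.991 to 0.998, and the highest correlation between arrays of different lines was 0.911. The median residual SD of a gene was 0.0916 on the log2 scale.

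Many genes differed between R406 and DMSO in every line, and most differences were small. At 6 h, 2998 genes were higher and 3142 lower in DHL4, 2333 higher and 2329 lower in DHL6, and 2988 higher and 2635 lower in LY7. HBL1 had 1309 higher and 1314 lower, and U2932 had 2101 higher and 1241 lower. At 24 h the numbers were 3656 and 4469 in DHL4, 2961 and 4174 in DHL6, 3139 and 3826 in LY7, 2508 and 2619 in HBL1, and 1896 and 2407 in U2932. The U2932 comparison at 6 h includes the array with the highest residual SD of all, DMSO replicate A, at 0.164. Without this array 2444 genes were called in U2932 at 6 h in place of 3342. The median absolute log2 fold change of the called genes lay between 0.261 in U2932 and 0.375 in DHL4 at 6 h, and between 0.285 in U2932 and 0.485 in DHL4 at 24 h. Changes of 2-fold or more were found at 24 h for 1376 called genes in DHL4, 410 in DHL6, 616 in LY7, 182 in HBL1 and 93 in U2932. At 6 h the corresponding numbers were 451, 177, 261, 95 and 38. Whether more genes were higher or lower depended on the scaling at 24 h in every line except DHL6. The share of called genes that were higher was 45.0% in DHL4, 45.1% in LY7, 48.9% in HBL1 and 44.1% in U2932, and became 52.0%, 55.7%, 52.5% and 55.5% with cyclic loess. With the median of each array subtracted it was 36.4%, 44.4%, 52.7% and 33.2%. In DHL6 it was 41.5%, with 47.1% after cyclic loess and 29.2% with medians subtracted. At 6 h the majority turned in DHL4, where the share was 48.8%, 55.2% with cyclic loess and 52.3% with medians subtracted.

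**Figure D1:**
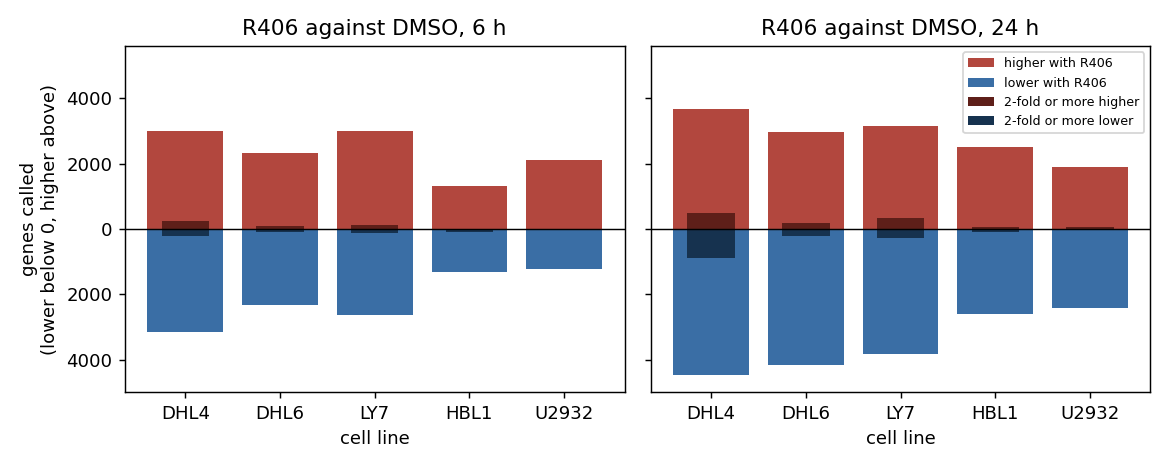
Number of genes called changed by R406 against DMSO (vertical axis, genes higher above 0 and genes lower below 0) in each cell line at 6 and 24 h; the narrow dark bars are the called genes that changed 2-fold or more. At 24 h DHL4 had 905 genes that were lower by 2-fold or more and U2932 had 47.

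The spread of the log2 fold changes over genes, corrected for their standard errors, was larger in DHL4, DHL6 and LY7 than in HBL1 and U2932. At 24 h it was 0.664, 0.447 and 0.497 in the first set and 0.317 and 0.262 in the second. At 6 h it was 0.426, 0.297 and 0.360 against 0.222 and 0.204. With the 5-prime probe set of 28S ribosomal RNA and the 3-prime minus 5-prime difference of beta-actin as covariates, the values at 24 h were 0.672, 0.583 and 0.626 against 0.375 and 0.537. The gap between DHL6, the lowest of the 3, and the highest of the other lines was then 0.0462 in place of 0.130. DHL4, DHL6 and LY7 are commonly classed as germinal centre B-cell type and HBL1 and U2932 as activated B-cell type.

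On average over the 5 lines, 3777 genes rose and 3421 fell at 6 h, and 3957 rose and 4692 fell at 24 h (15 arrays in each condition). At 24 h the majority that fell depended on the scaling, since the share of called genes that rose was 45.8% but 52.7% with cyclic loess, and 38.4% with medians subtracted. Of the genes called at 6 h, 2851 had the same sign in all 5 lines, with 1595 higher and 1256 lower. At 24 h there were 3713, with 1514 higher and 2199 lower. Independent signs would give 6.25% of all genes the same sign in 5 lines, and the measured share was 25.6% at 6 h and 31.9% at 24 h. At 6 h, 253 genes were called higher and 160 lower in each of the 5 lines, where independent lists of these lengths would share 3.02 and 1.65. At 24 h, 364 were called higher and 883 lower in every line, against 8.49 and 23.6. These calls treat the 5 lines as fixed. When the spread between the lines was used in place of the spread between arrays, limma called 32 genes at 6 h and 0 at 24 h, with 3194 and 3657 genes at an unadjusted p under 0.05.

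The gene with the highest average response that had the same sign in all lines was ENSG00000092758 at both times. It rose by 2.00 ± 0.05 (SE) on the log2 scale at 6 h (adjusted p = 2.62e-39) and by 2.43 ± 0.05 at 24 h (adjusted p = 3.14e-44). In LY7 at 6 h its level was 10.7 ± 0.14 (SD, n = 3) in R406 and 6.80 ± 0.048 (SD, n = 3) in DMSO. In DHL6 at 24 h it was 10.1 ± 0.069 (SD, n = 3) and 5.90 ± 0.094 (SD, n = 3). Its smallest change was in DHL4 at 6 h, at 0.26 ± 0.11 (SE, adjusted p = 0.0377), and this call was lost without the filter (adjusted p = 0.0592) and with any of the 6 arrays of that comparison left out except DMSO replicate C (lowest 0.15, adjusted p = 0.301, without DMSO replicate A). Its rise of 0.66 in HBL1 at 6 h became 0.07 (adjusted p = 0.705) against DMSO at 0 h. ENSG00000176809 had the next highest average at 24 h, 2.03 ± 0.10 (SE, adjusted p = 1.00e-25). It rose by 3.88, 3.32 and 2.48 in DHL4, DHL6 and LY7 at 24 h, while its changes of 0.16 in HBL1 and 0.32 in U2932 did not pass the threshold (adjusted p = 0.607 and 0.275). Its DMSO level at 24 h was below the filter level of 5.89 in every line, at 5.19 ± 0.35 in DHL4, 4.20 ± 0.11 in DHL6, 3.10 ± 0.10 in LY7, 2.99 ± 0.14 in HBL1 and 3.00 ± 0.21 in U2932 (SD, n = 3). In LY7 its R406 level of 5.58 ± 0.18 (SD, n = 3) was below it too. The sizes of changes from such low levels are uncertain.

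Among genes with the same sign in all lines, ENSG00000226397 fell most on average at 6 h and ENSG00000117009 at 24 h. ENSG00000226397 had an average log2 fold change of -1.80 ± 0.07 (SE, adjusted p = 6.02e-29) at 6 h and -1.55 at 24 h (adjusted p = 1.49e-26). Its level in DHL4 at 6 h was 4.53 ± 0.19 in R406 and 7.61 ± 0.11 in DMSO (SD, n = 3). Its R406 level was below 5.89 in every line at both times, so the size of its fall is uncertain. In LY7 its DMSO level at 24 h was 4.09 ± 0.21 and the change of -0.26 did not pass the threshold (adjusted p = 0.180), though it did with array weights (-0.32, adjusted p = 0.0492) and against DMSO at 0 h (-0.44, adjusted p = 0.0186). ENSG00000117009 had an average of -1.81 ± 0.03 (SE, adjusted p = 6.34e-46) at 24 h and -1.73 ± 0.03 (adjusted p = 2.43e-44) at 6 h, and was called lower in all 5 lines at both times. In HBL1 its R406 level was below 5.89 at both times, at 4.80 ± 0.14 at 6 h and 5.17 ± 0.059 at 24 h (SD, n = 3). In U2932 it was 5.43 ± 0.035 at 6 h, also below that level, and 5.89 ± 0.11 at 24 h. Its largest change was in DHL6 at 24 h, where it measured 6.23 ± 0.071 in R406 and 9.54 ± 0.065 in DMSO (SD, n = 3). The log2 fold changes of all 4 genes differed among the lines at both times by the F-test. For a pair of them this rests in part on lines below the filter level in both conditions at both times. ENSG00000226397 had DMSO levels of 4.09 to 4.30 in LY7 and 4.25 to 4.78 in U2932, and ENSG00000176809 lay at 2.86 to 3.15 in HBL1, 3.00 to 3.58 in U2932 and 3.10 to 5.58 in LY7 in R406 and DMSO. How far their responses differ among the lines is therefore uncertain.

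**Figure D2:**
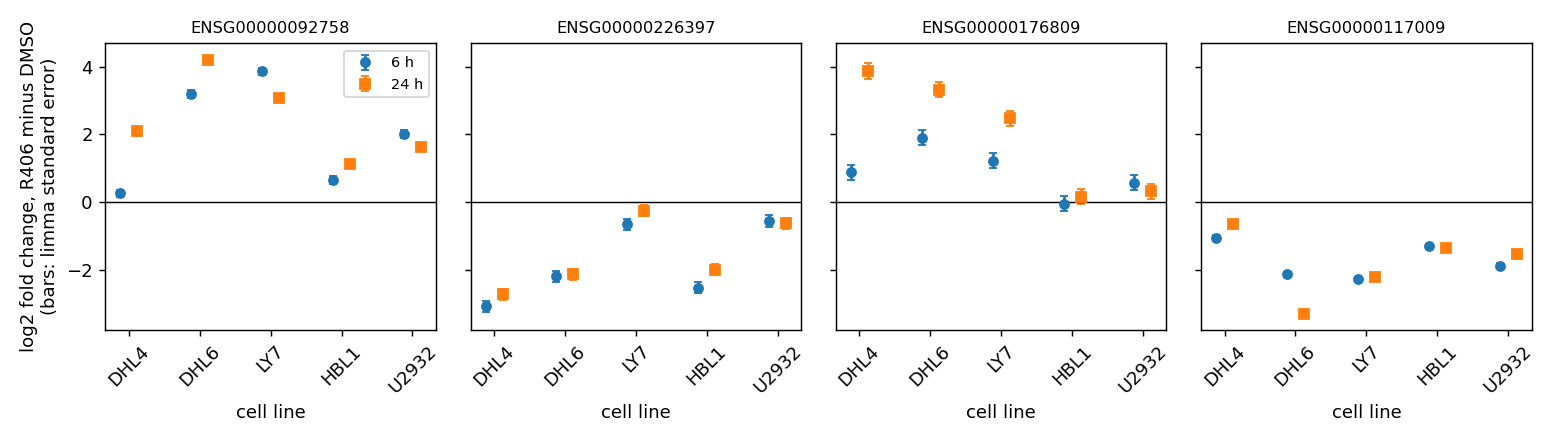
Log2 fold change of R406 against DMSO (vertical axis, limma estimate with its standard error as the bar) in each cell line for the 4 identified genes, with circles for 6 h and squares for 24 h. ENSG00000117009 lay below 0 in every line at both times, and ENSG00000176809 at 24 h lay between 2.48 and 3.88 in DHL4, DHL6 and LY7 and at 0.16 and 0.32 in HBL1 and U2932, from DMSO levels below 5.89 in every line.

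The response to R406 differed among the 5 lines for 7440 genes (63.3%) at 6 h and for 9716 genes (82.7%) at 24 h. The mean response of HBL1 and U2932 differed from that of DHL4, DHL6 and LY7 for 5204 genes at 6 h and 6964 genes at 24 h, and by 2-fold or more for 149 and 265 of them. The difference was positive for 2835 genes at 6 h and 4256 at 24 h. At 6 h this share was 54.5%, and 42.6% with cyclic loess. At 24 h it was 61.1%, with 52.1% after cyclic loess and 68.3% with medians subtracted. With the lines as replicates, limma called 0 genes at either time, with 1583 and 1117 genes at an unadjusted p under 0.05. The correlation of log2 fold changes over genes, which are not independent replicates, was 0.629 between DHL4 and DHL6 at 6 h, 0.579 between DHL4 and LY7 and 0.530 between DHL6 and LY7. Correlations of these 3 lines with HBL1 and U2932 ranged from 0.185 to 0.380 at 6 h, and HBL1 and U2932 correlated at 0.353. At 24 h the 3 correlations were 0.621, 0.502 and 0.507, those across the sets ranged from 0.317 to 0.439, and HBL1 and U2932 correlated at 0.416. No arrays are shared between these contrasts.

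The responses at 6 and 24 h overlapped within each line. The correlation over genes of the log2 fold changes at the 2 times was 0.665 in DHL4, 0.628 in DHL6, 0.754 in LY7, 0.557 in HBL1 and 0.510 in U2932, with no arrays shared. In LY7, 4161 genes (74.0% of those called at 6 h) were called in the same direction at 24 h, where 1657 were expected from independent lists, and 377 in the opposite direction against 1678 expected. In U2932, 1494 genes (44.7%) were called in the same direction, with 593.5 expected, and 228 in the opposite direction. This overlap was not computed again without DMSO replicate A of U2932 at 6 h, the array with the highest residual SD. Both times share 1 variance estimate per gene, so the numbers expected from independent lists are likely too low. The average response differed between 24 and 6 h for 6903 genes, of which 2655 had the higher value at 24 h and 4248 the lower. The share with the higher value was 38.5%, and 49.1% with cyclic loess or 27.9% with array medians subtracted. The difference reached 2-fold for 25 of these genes, 23 of them with the higher value at 24 h. With the lines as replicates 20 genes were called, and 2852 had an unadjusted p under 0.05.

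In DMSO alone, 2694 genes were higher and 2167 lower at 6 h than at 0 h on average over the lines, and 2950 were higher and 1977 lower at 24 h. At 6 h the share that was higher was 55.4%, and 50.0% with cyclic loess. Their median absolute log2 fold change was 0.140 at 6 h and 0.138 at 24 h among called genes, and 14 and 12 genes changed 2-fold or more. With the lines as replicates 23 genes were called at 6 h and 381 at 24 h. For R406 the medians of the average responses were 0.184 and 0.244, and 40 and 170 called genes changed 2-fold or more. At 0 h, 8526 genes differed between the 2 sets of lines, 4080 of them higher in HBL1 and U2932 and 4446 lower, and 1170 by 2-fold or more. The gene lists meant to describe this difference were not used here.

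Control probe sets of abundant human RNAs also changed with R406. The 5-prime probe set of 28S ribosomal RNA, a part of the large ribosomal subunit, was higher at 24 h by 1.80 ± 0.06 (SE) in DHL6 (adjusted p = 7.26e-35), 1.91 ± 0.06 in U2932 (adjusted p = 5.64e-36), 0.93 in DHL4 and 0.65 in HBL1. In LY7 its log2 fold change was -1.54 ± 0.06 (SE, adjusted p = 1.26e-31). In LY7 its level at 24 h was 11.5 ± 0.023 in R406 and 13.1 ± 0.044 in DMSO (SD, n = 3). At 6 h it was lower in LY7 as well (-1.12, adjusted p = 5.16e-25) and higher in the other 4 lines, by 0.19 in HBL1 to 0.74 in DHL6. The middle probe set of 28S moved the same way at 24 h, with -0.56 in LY7 and 0.32 to 0.87 in the other lines. Its 3-prime probe set had levels of only 5.56 to 6.06 at 24 h, around the filter level of 5.89. At 24 h this probe set was called higher in DHL6 (0.38, adjusted p = 0.000558), DHL4 (0.26, 0.0201) and U2932 (0.25, 0.0232), but not in HBL1 (0.849). The call in DHL4 was lost with cyclic loess (0.212) and medians subtracted (0.115), and that in U2932 with medians subtracted (0.0528). Without R406 replicate B the change in DHL4 was only 0.04 (adjusted p = 0.757), so it rested largely on that array. The DHL4 call was lost as well with array weights (0.106) and without DMSO replicate B (0.0958) or C (0.0912). In LY7 the level of the 3-prime probe set was 5.60 ± 0.12 in R406 and 5.63 ± 0.062 in DMSO (SD, n = 3), so it does not show whether its part of 28S changed.

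The probe sets of 18S ribosomal RNA, a part of the small subunit, were bright in every line. At 24 h the middle one was lower in LY7 (-0.55, adjusted p = 1.69e-05) and higher in DHL6 (0.39) and U2932 (0.46), while DHL4 and HBL1 did not pass the threshold (adjusted p = 0.368 and 0.542). The 3-prime one was higher in DHL6 (0.83) and U2932 (1.07), and its value in LY7 was -0.09 (adjusted p = 0.577). It did not pass in DHL4 (0.21, adjusted p = 0.119), though it did with cyclic loess (0.50) and without DMSO replicate B (adjusted p = 0.0456), nor in HBL1 (0.18, adjusted p = 0.179), though it did without DMSO replicate C (adjusted p = 0.0221). The 5-prime values were -0.26 in DHL4, -0.22 in LY7, 0.27 in DHL6 and 0.27 in U2932, and none of these kept its call under every alternative. The values in DHL4 and LY7 turned to 0.028 and 0.0096 with cyclic loess. The DHL4 call was also lost with array weights (adjusted p = 0.0667) and without DMSO replicate C (0.181) or R406 replicate A (0.133). The LY7 call, with an adjusted p of 0.0482, was lost without the filter (0.0507) and without many single arrays, of which R406 replicate A (-0.11, adjusted p = 0.400) moved it most. The call in DHL6 was lost with medians subtracted (adjusted p = 0.0898) and without DMSO replicate C (0.0711) or R406 replicate A (0.15, adjusted p = 0.236), and that in U2932 without R406 replicate A (0.0609).

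The 5-prime probe set of beta-actin, a main protein of the cytoskeleton, fell at 24 h in DHL6 (-0.87 ± 0.10, SE, adjusted p = 2.42e-10) and LY7 (-0.95 ± 0.10, adjusted p = 1.71e-11). It was also lower in U2932 (-0.32, adjusted p = 0.00954), a call that was lost without R406 replicate B (adjusted p = 0.0656). In DHL4 it was lower by the values as deposited (-0.30, adjusted p = 0.0151), but not with cyclic loess (-0.01, adjusted p = 0.945) or without DMSO replicate C (0.0561), R406 replicate B (0.0591) or R406 replicate C (0.0522). In HBL1 its change of -0.13 did not pass the threshold (adjusted p = 0.324). The middle and 3-prime probe sets of beta-actin also fell at 24 h in DHL6 (-0.74 and -0.42) and LY7 (-0.86 and -0.53). Neither passed the threshold in DHL4 (adjusted p = 0.067 and 0.849), HBL1 (0.121 and 0.433) or U2932 (0.33 and 0.221). With medians subtracted both were called lower in DHL4 (0.00435 and 0.0467), and the 3-prime one in U2932 (0.0467). With cyclic loess the middle one was 0.14 in DHL4 (adjusted p = 0.0599), and the 3-prime one was called higher there (0.26, 1.19e-08). In U2932 the 3-prime one was then 0.02 (0.67). The direction in DHL4 thus depended on the scaling. The difference between the 3-prime and 5-prime probe sets of beta-actin, a sign of RNA quality, rose by 0.30 on average at 24 h (adjusted p = 9.06e-08), while that of GAPDH did not pass the threshold (adjusted p = 0.725). These GAPDH probe sets lay at 13.6 to 14.31 at 24 h, close to the highest value of all, 14.76. Their difference may therefore be a weak measure of RNA quality. The middle probe set of GAPDH, a glycolytic enzyme, fell at 24 h in DHL6 (-0.24), LY7 (-0.33) and U2932 (-0.19), by less with cyclic loess though still past the threshold, and in DHL4 by the values as deposited (-0.23, adjusted p = 3.36e-11) but not with cyclic loess, where its change was 0.03. The 3-prime probe set of ISGF3A, a subunit of an interferon-activated transcription factor, fell at 24 h in DHL4 (-0.85 ± 0.06, SE, adjusted p = 3.43e-17) and HBL1 (-0.53 ± 0.06, adjusted p = 4.09e-10). In DHL6 it was lower as well (-0.20, adjusted p = 0.00924), which was lost with cyclic loess (-0.08, adjusted p = 0.367) and without DMSO replicate B (0.0572) or R406 replicate C (0.072). In U2932 its value of -0.14 did not pass (adjusted p = 0.0766), though it did with medians subtracted (0.0277) and with array weights (0.0191). In LY7 its value was -0.01 (adjusted p = 0.901), and 0.10 (adjusted p = 0.267) with cyclic loess. At 6 h it was higher in DHL6 (0.27, adjusted p = 0.000338) and U2932 (0.27, 0.000347) and lower in HBL1 (-0.27, 0.000377). It did not pass in LY7 at 6 h (-0.10, adjusted p = 0.225). In DHL4 it was higher at 6 h (0.17, adjusted p = 0.0287), a call lost without some single arrays, such as R406 replicate C (0.172). One of the middle probe sets was lower in HBL1 at 24 h (-0.67, adjusted p = 4.49e-08), with levels of 6.99 ± 0.19 in R406 and 7.66 ± 0.0074 in DMSO (SD, n = 3). It did not pass the threshold in the other lines, where its levels were 6.06 to 6.48. The other middle probe set was lower in HBL1 (-0.41, adjusted p = 0.00497) at levels of 6.32 and 6.74. In DHL4, DHL6 and U2932 that probe set lay below 5.89 in both conditions, as did the 5-prime one in every line (3.91 to 4.43), and their changes there are not read.

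Spike-in RNAs, which do not come from the cells, also differed. The hybridisation controls were higher with R406 at 24 h by 0.42 on average (adjusted p = 1.89e-11), most in DHL4 (0.84), and the poly-A spikes by 0.25 on average (adjusted p = 3.04e-05), with -0.56 in DHL4 and 0.67 in DHL6. Both averages lay above 0.244, the median absolute log2 fold change of the genes called on average at 24 h. How far small changes of genes share in what moved the spikes was not tested. With the 5-prime 28S probe set and the actin difference as covariates, the number of genes called at 24 h was 4855 in DHL4, 1708 in DHL6, 2343 in LY7, 1104 in U2932 and 3807 on average, and at 6 h it was 2097 in LY7. The other counts of that fit stayed within 1.5 times, with 3587 in HBL1 at 24 h, and at 6 h 5591 in DHL4, 3287 in DHL6, 2809 in HBL1, 3642 in U2932 and 7103 on average. The standard errors were larger in that fit, at a median of 0.142 in HBL1 to 0.367 in U2932 at 24 h in place of 0.0742.

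**Figure D3:**
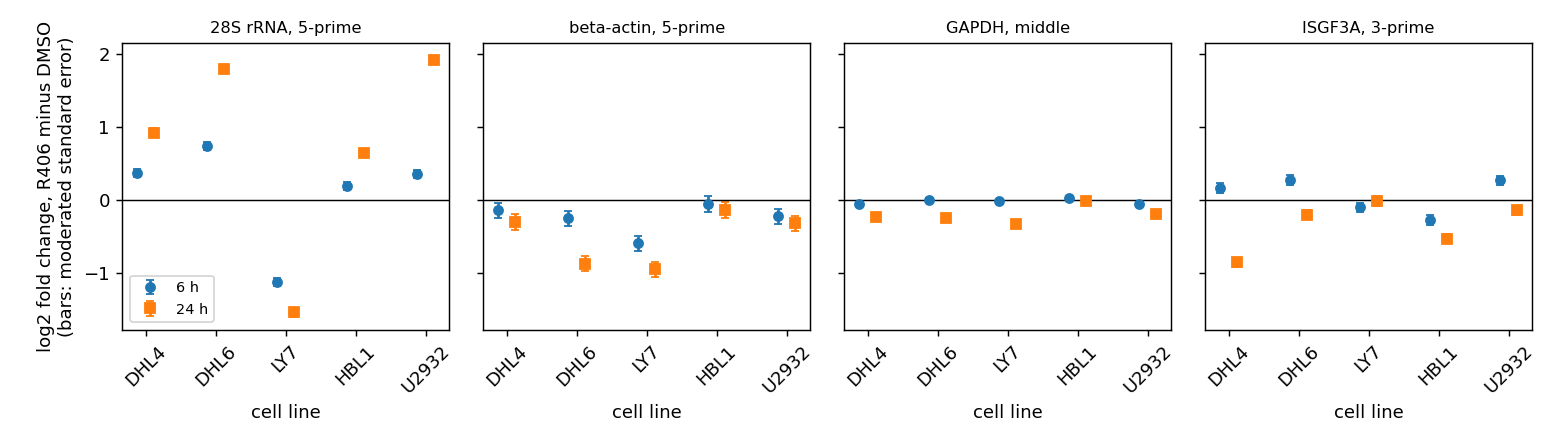
Log2 fold change of R406 against DMSO (vertical axis, with its moderated standard error as the bar) of 4 control probe sets in each cell line, with circles for 6 h and squares for 24 h. The 5-prime 28S probe set lay at 1.80 in DHL6 and at -1.54 in LY7 at 24 h.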

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

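The tests on the splits of the 6 arrays within each line, the split counts for genes with the same sign in all 5 lines, the test of noisier arrays and the test of RNA degradation were chosen after the results they concern were seen. The rule that opposite changes past the threshold count against an explanation of the 28S pattern was also set after its values were seen.

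Each of these results was singled out because the response to R406 differed between lines or times by a test of the difference itself. They are the 7440 genes at 6 h and 9716 genes at 24 h whose response differed among the 5 lines, the 5204 and 6964 genes that differed between the 2 sets of lines, and the 6903 genes whose average response differed between 24 and 6 h. The adjusted p of the F-test over lines, at 6 and 24 h in this order, was 3.24e-28 and 4.95e-43 for the 5-prime probe set of 28S rRNA, 0.0127 and 5.22e-07 for that of beta-actin, and 3.25e-07 and 5.29e-12 for the 3-prime probe set of ISGF3A. For the middle probe set of GAPDH it was 7.75e-10 at 24 h. For the identified genes it was 1.47e-29 and 2.80e-25 (ENSG00000092758), 8.33e-16 and 5.05e-15 (ENSG00000226397), 8.81e-06 and 7.31e-18 (ENSG00000176809), and 2.27e-16 and 1.11e-28 (ENSG00000117009). ENSG00000226397 in LY7 and U2932, and ENSG00000176809 in LY7, HBL1 and U2932, lay below the filter level of 5.89 in both conditions, so their differences among lines are uncertain in size.

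Chance assignment of single arrays was argued against for the averages. If the letters are not separate cultures, chance differences between cultures are not covered by these splits. Of 100 splits within the lines, 1, the real one, called as many genes. The real numbers and the highest of the other splits were 7198 and 2465 at 6 h and 8649 and 5517 at 24 h for the average, 2851 and 700 at 6 h and 3713 and 2931 at 24 h for genes with the same sign in all lines, and 7440 and 2096 at 6 h and 9716 and 7100 at 24 h for differences among lines. For DMSO over time they were 4861 and 3340 at 6 h and 4927 and 843 at 24 h, and for 24 h against 6 h 6903 and 573. The arrays were split separately in each line, so other splits could keep the real grouping of single lines. The highest of the other splits can therefore hold real differences and are not the level that chance alone would give.

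Within a line there are only 10 splits of 6 arrays, too few for a share under 0.05. The real number and the highest other at 6 h were 6140 and 11 in DHL4, 4662 and 5 in DHL6, 5623 and 9 in LY7, 2623 and 7 in HBL1, and 3342 and 462 in U2932. At 24 h they were 8125 and 225, 7135 and 1062, 6965 and 4, 5127 and 25, and 4303 and 3. The 5 lines also give only 10 splits into 2 and 3. At 6 h the real number of 5204 stood against a highest other of 5108, and at 0 h 8526 against 8475. At 24 h 2 of the 10 splits gave as many as the real 6964, the other being DHL4 and DHL6 against the rest with 7527. Each of the 10 pairs of lines differed from the remaining lines for at least 2613 genes at 6 h and 4713 at 24 h.

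The larger responses of DHL4, DHL6 and LY7 at 24 h were weighed first. Noisier arrays in these lines would widen their spread, and the residual SD of the 24 h arrays was 0.124 in DHL4, 0.124 in DHL6, 0.0982 in LY7, 0.105 in HBL1 and 0.0948 in U2932. For noise between the arrays of a group this was argued against. With each line's spread corrected by its own 24 h arrays, the lowest of the 3 lines lay 0.126 above the highest of the other 2. At least 0.961 of the uncorrected difference was kept with any array left out. Noise shared by all arrays of a group would not be seen this way. A change in RNA quality stays open: with the 28S probe set and the actin 3-prime minus 5-prime difference as covariates, 0.356 of the difference was kept (0.0462 in place of 0.130, each corrected with the standard errors of its own fit over all lines), while the median standard error at 24 h grew from 0.0742 to 0.344 in DHL6 and 0.367 in U2932, so that this fit cannot decide. In that fit the spread did not fall in DHL4, DHL6 or LY7 (0.672, 0.583 and 0.626 in place of 0.664, 0.447 and 0.497). It rose most in U2932, from 0.262 to 0.537, which narrowed the difference. A difference in the biology of the lines is also open, as is any other difference between 5 lines.

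The 5-prime and middle probe sets of 28S moved in opposite directions in LY7 and the other lines at 24 h. RNA degradation would be seen in the actin 3-prime minus 5-prime difference, which had the sign of the 5-prime 28S change in 7 of 10 comparisons of line and time, but in 2 comparisons, both in LY7, the measures passed the threshold in opposite directions. A lower share of mRNA in the labelled RNA would raise the poly-A spikes along with 28S. They had its sign in 7 of 10 comparisons too, and in 2, LY7 and DHL4 at 24 h, the measures were past the threshold in opposite directions. Neither explanation covers all lines, and a change in ribosomal RNA itself was not tested.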

How the results depend on the processing

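The covariates and all alternatives for the control probe sets and the cell-cycle lists were chosen after the data were seen. Of 1872 values of the 22 gene counts under alternatives, 1859 lay within 1.5 times the reported count. This held for each alternative except the lines as replicates and the covariates, and leaving out any array never moved a count further. Most of the 1872 values are refits with 1 of the 75 arrays left out. A count for 1 line and time compares only 6 arrays, so most of these refits could hardly move it. With the lines as replicates, R406 on average gave 32 genes at 6 h and 0 at 24 h, the sets differed for 0 genes at 6 h and 0 at 24 h, 24 h against 6 h gave 20, and DMSO over time gave 23 at 6 h and 381 at 24 h. Here 5 lines stand in for the arrays, and the lines differ in their response. With the 28S probe set and the actin difference as covariates the counts were 2097 in LY7 at 6 h, and at 24 h 4855 in DHL4, 1708 in DHL6, 2343 in LY7, 1104 in U2932 and 3807 on average; the standard errors grew with these covariates. With the replicate letter as a block, the average gave 7225 genes at 6 h and 8674 at 24 h, and no count moved by over 1.5 times. Residuals of arrays with the same letter in a line had a mean correlation of 0.00638, 34 of 150 pairs were above 0.1, and 25 of 75 arrays were closest to their own letter, so the letters were not used as pairs. The middle GAPDH probe set changed sign with cyclic loess in DHL6 (0.07605) and LY7 (0.07585) at 6 h, where it had not passed the threshold and then passed it in the opposite direction (adjusted p = 0.0181 and 0.0183), and in DHL4 (0.03265) at 24 h, where its call was lost. Its values that passed in neither case also changed sign with cyclic loess in DHL4 (0.008066) and on average (0.02543) at 6 h and in HBL1 at 24 h (0.01045), and with medians subtracted in DHL6 at 6 h (0.00682) and HBL1 at 24 h (0.001597). The 5-prime probe set of 18S did so in DHL4 (0.02839) and LY7 (0.009555) at 24 h, and the 3-prime probe set of beta-actin in DHL4 at 24 h, from -0.01 (adjusted p = 0.849) to 0.2614 (adjusted p = 1.19e-08); the cause was not tested. The stricter filter tested 6913 genes and no filter 19536. The alternatives of the preset gene lists, and the mean of probe sets per gene, were not run. Signal near the floor limits what can be seen in dim genes.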

Other observations

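The cell-cycle lists were written after the numbers of called genes were known and before the fold changes of any list, and their alternatives were chosen later. The tests below were fixed before their results were seen, except that a call had also to hold with an estimated correlation, and that a correlation above 0 with any array left out counts against a shift in every line, which were decided after.

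Lists of genes with higher expression in G1, S or G2/M were taken by identifier from marker pairs for human embryonic stem cells, so they are not B-cell lists. Of the G2/M list, 147 of 170 genes were tested. On average over the lines at 6 h, 92 rose, 25 fell and 30 did not pass the threshold (94 rose and 25 fell adjusted over the list alone), with a median log2 fold change of 0.14. Relative to the other genes the list was higher (limma camera, adjusted p = 1.05e-07; adjusted p = 0.0177 with an estimated correlation), and the adjusted p stayed between 6.43e-08 and 1.72e-07 with any array left out. In single lines at 6 h camera called it higher in all 5, and with an estimated correlation this held in DHL4 (adjusted p = 0.0396), DHL6 (0.0305) and U2932 (0.0227) but not in LY7 (0.381) or HBL1 (0.0954). Control measures moved on average at 6 h as well: the 5-prime 28S probe set by 0.11 (adjusted p = 0.00043), the actin 3-prime minus 5-prime difference by 0.12 (adjusted p = 0.0472) and the poly-A spikes by 0.15 (adjusted p = 0.0307). The actin and poly-A calls were lost when any 1 of several arrays was left out, with adjusted p values of up to 0.156 (without U2932 R406 replicate A at 6 h) and 0.0762 (without DHL6 DMSO replicate A at 6 h). At 24 h 56 of these genes rose and 65 fell. Its median at 24 h was -0.02, while camera gave the direction up (adjusted p = 0.546). Without the filter the direction was down (adjusted p = 0.947), and against DMSO at 0 h the list was called higher (adjusted p = 0.0499). In DMSO alone 60 of its genes rose and 26 fell at 6 h (camera, adjusted p = 0.0157; adjusted p = 0.282 with an estimated correlation), and 70 rose and 20 fell at 24 h (adjusted p = 0.00133; adjusted p = 0.219 with an estimated correlation). Of the S list in DMSO 31 rose and 54 fell at 6 h (adjusted p = 0.0157; adjusted p = 0.207 with an estimated correlation). Of the G1 list 88 genes rose and 56 fell on average at 6 h with R406 (adjusted p = 0.122), a list that was called higher without the filter (adjusted p = 0.0146) and without DHL6 (adjusted p = 0.0415), and in U2932 alone (adjusted p = 0.003; adjusted p = 0.0471 with an estimated correlation). Of the S list 65 rose and 46 fell (adjusted p = 0.314), and its direction was down against DMSO at 0 h (adjusted p = 0.639). Limma's fry tests the genes of a list alone, not relative to other genes. It called the G1 and S lists higher on average at 6 h (adjusted p = 2.51e-11 and 1.4e-05).

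At 24 h the S list had 40 genes that rose and 100 that fell among 167 tested, with a median of -0.12, and the G1 list had 56 that rose and 104 that fell among 179, with a median of -0.14. The hypothesis that the lists fall at 24 h was tested with limma's camera on the average over the lines (n = 15 arrays in each condition), which gave p = 0.00601 for S, 0.0164 for G1 and 0.546 for G2/M. The adjusted p was 0.018 for S and 0.0246 for G1. The S and G1 calls were lost with an estimated correlation (adjusted p = 0.138 for both), with the stricter filter (0.219 for both), without LY7 (0.0678 for both) and with cyclic loess (0.112 for S and 0.328 for G1), and G1 also without DHL6 (0.0797). Without the filter both had an adjusted p of 7.11e-05. Both calls held with camera on ranks (adjusted p = 0.0135 for S and 0.0292 for G1). Fry, which does not compare a list with other genes, gave both as lower (adjusted p = 1.68e-30 for S and 1.8e-33 for G1). In single lines at 24 h, the calls that held with an estimated correlation were S in LY7 (adjusted p = 0.0276) and G1 in DHL6 (adjusted p = 0.0486), and those of S in DHL6 (0.130), G1 in LY7 (0.0878) and G2/M, called higher in HBL1 (0.407), were lost. On average at 24 h the 5-prime 28S probe set was higher by 0.75 and the actin difference by 0.30. In single lines camera on ranks and fry were also run. Camera on ranks gave an unadjusted p of 9.56e-05 for S in LY7 and 0.000317 for G1 in DHL6. For the lost calls it gave 0.00394 (S in DHL6), 0.0108 (G1 in LY7) and 0.00638 (G2/M in HBL1). Fry also gave a small p where camera called nothing, as for G1 in DHL4 (7.68e-29). Other scalings, filters and left-out arrays were not run for single lines. So a fall of the S and G1 lists relative to other genes on average may not hold and stays undecided.

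A further hypothesis was that R406 moves each line away from its own starting profile, so that genes higher in a line at 0 h than in the other 4 would fall. The correlation over genes of the 0 h deviation with the response was below 0 in 7 of 10 comparisons of line and time, most in HBL1 (-0.23 at 6 h and -0.27 at 24 h). In LY7 it was 0.0107 and 0.032, above 0 with any array left out, while the rank correlations there were only 0.0017 and 0.00282. No such shift was thus seen in LY7, which by the rule set afterwards argues against one in every line. By the rule fixed before, 7 of 10 left the question undecided. R406 could also narrow the difference between the 2 sets of lines. The correlation of the set difference at 0 h with the set difference in response at 24 h was -0.127, but all 10 divisions of the lines gave values below 0, from -0.208 to -0.127, so nothing particular to these sets was seen.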
